A study of Mus musculus with 3 samples.

How the data were processed

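Spleen CD4+ T cells were taken from C57BL/6J mice aged 6 to 12 weeks, 7 days after infection with red cells carrying the rodent malaria parasite Plasmodium chabaudi chabaudi AS. Per the labels' protocols, each of 5 mice received its own hashtag antibody, polyclonal cells with high CD11a and surface CXCR3 were sorted, and T cell receptor transgenic cells were sorted apart and added at 1 part to 9. About 33000 cells were loaded on 1 droplet channel, and gene expression, T cell receptor and hashtag libraries were made with a 5' kit and converted for a BGI sequencer. The 3 libraries hold the same pool of cells, so the mouse, read from the hashtag, was the replicate in every comparison of genes, lists, V segments and shares. The tests of clonotypes permuted class labels over cells within each mouse, and binomial intervals count cells, so these describe the cells of these mice.

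The deposited matrix holds counts of unique molecular identifiers (UMIs) per gene or hashtag and cell barcode, not normalised, made with Cell Ranger 6.1.1 per the file headers and against build mm10 per the submitters' processing notes. The authors' receptor table gives counts of reads and UMIs per assembled contig, and each contig in it was productive and full length. The cell calling settings, the annotation release and the read filters are not given in the sources used here. The matrix held 16465 barcodes and 141253151 gene UMIs, with a median of 7062 UMIs and 2447 genes per barcode. There were 59099873 hashtag UMIs, and 28030 contigs in 12911 barcodes (78.4%). No column of per-sample values was left unmatched.

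Hashtags were called with HTODemux of Seurat 5.3.0 at a positive quantile of 0.99. A single hashtag was called in 13985 barcodes, more than 1 in 2476 (15.0%) and none in 4. Cells needed at least 500 genes, under 10% mitochondrial counts, 1 hashtag and not more than 1 productive TRB chain, and 13124 were kept. Doublets of cells from 1 mouse carry 1 hashtag and can remain; Scrublet with an expected rate of 0.1 called 1442 of the 16331 barcodes that passed the limits on genes and mitochondrial counts (8.83%), 398 of them among the kept cells, and their removal was an alternative. A clonotype was a mouse, a TRBV segment, the TRB nucleotides of the third complementarity-determining region (CDR3) and the TRA CDR3 nucleotides with most UMIs. The transgenic-like receptor was the paired clonotype with most cells in the pool, accepted because it occurred under all 5 hashtags. Cells with a GFP UMI or either transgenic-like chain were left out of the polyclonal cells, which numbered 11904, except in the comparison of transgenic-like cells, which was against all other kept cells with a paired receptor.

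Clustering used scanpy 1.11.5 with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, without cell cycle and receptor genes among the variable genes. Clusters were named from marker lists fixed before the data were examined, so the names rest on transcripts and not on the authors' annotation, which was not used here. Because a gene that defines a class cannot be tested between classes, genes were split at random into 2 parts with seed 1. Classes used to test 1 part were clustered from the other part and the fixed markers, and the markers themselves were not tested between Th1-like and Tfh-like cells. Class shares, clonotype tests and comparisons within Th1-like or Tfh-like cells alone used classes clustered from all genes, without this split.

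Counts were summed per mouse and group, with at least 10 cells per sum, and tested with edgeR 4.0.16 (R 4.3.3), using its quasi-likelihood test, TMM factors, filterByExpr and mouse as a block, with Benjamini-Hochberg adjustment at 0.05. Every adjusted p given for a gene or V segment is from this two-sided test. Receptor and immunoglobulin segments were not tested as genes. Per comparison, the named genes were the 8 with the highest and the 8 with the lowest log2 fold change among those past the threshold, changed the same way in every mouse and at 20 or more CPM, counts scaled by library size, in a group, leaving out markers, receptor genes and predicted genes. To these were added, per gene list, the 3 tested members with the smallest adjusted p, and Cxcr3, Itgal and Cd4, the genes of the sorted proteins. Of V segments the 3 with the smallest adjusted p were named. These rules, the gene lists, the markers, the designs and the first set of alternatives were fixed before the data were examined. The text gives values or ranges for all of the 8 highest and 8 lowest genes and values for some of the list members; the other list members were left out for length, except 1 gene that is not reported here. The alternatives were computed for all of them.

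The lists covered cytotoxic granule and killer receptor genes, inhibitory receptors, the IL-10 or Tr1 programme, migration receptors, secreted and ligand cytokines, memory and quiescence, T cell receptor signal, type I interferon response, follicular helper accessory genes, Th1 accessory genes, glycolysis, oxidative phosphorylation, ribosome biogenesis, ribosomal proteins, S phase, G2 and M phase, dissociation stress and mitochondrial transcripts. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation was run beside it, and fry, which tests whether a list's genes move one way on balance, was a further alternative. With the estimated correlation only the Th1-like markers and the Th1 accessory genes between expanded and single-cell clonotypes kept an adjusted p under 0.05.

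Class shares and Th1-like shares were compared by a two-sided exact sign-flip permutation test over 5 mice, which cannot give a p below 0.063. Agreement within clonotypes was tested with 10000 permutations of class labels within each mouse, for which the smallest p is 0.0001. Sums of a mouse come from the same animal, which is where the pairing comes from. After group means were removed, the sums of 1 mouse correlated by 0.09 to 0.31 between Th1-like and Tfh-like cells, by 0.09 to 0.37 between expanded and single-cell clonotypes, and by 0.20 to 0.60 between transgenic-like and polyclonal cells. The correlations are across genes, which are not independent replicates. Intervals for shares of cells are exact binomial 95% intervals and cover counting error only. A floor of 3 counts over a group served for folds against a group at 0 counts.

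The tests were checked on simulated counts with 200 changed genes. Of genes changed 1.5-fold, 94% were recovered for Th1-like against Tfh-like cells, 64.2% for expanded against single-cell clonotypes and 83.6% for transgenic-like against polyclonal cells. At 2-fold these were 100%, 91% and 95.5%, and 9, 8 and 6 unchanged genes were called. The changed genes were drawn from those with many counts, and the simulation had a common dispersion and no difference between mice. The figures need not hold for scarcer or more variable genes. Alternatives covered the normalisation, DESeq2 1.42.0, the filter, the block, each mouse left out, cell quality, hashtag calls, doublets, clustering, clonotype definition, single classes and thinning to 3000 UMIs per cell. Gene coordinates are from GENCODE vM21 on GRCm38.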

Results

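The series measured gene expression, T cell receptor sequences and hashtags in the same pool of spleen CD4+ T cells from 5 mice, 7 days into blood-stage Plasmodium chabaudi infection. The labels give 1 time point and no uninfected group, so the comparisons lie between kinds of cells within the mice. After filters 13124 cells remained, between 1670 and 3935 per mouse, with 12268755 to 30909604 UMIs per mouse and a median of 6586 UMIs per cell. Paired receptors were read in 9777 of these cells.

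Cells with a follicular helper transcriptome were the most frequent of the classes named here. Tfh-like cells, which carried Cxcr5, Bcl6, Tcf7 and Il21 transcripts of T cells that help B cells, made up 41.6% ± 6.20 (SD, n = 5 mice) of polyclonal cells. Th1-like cells, which carried Ifng, Cxcr6, Ccl5 and Tbx21 transcripts of the interferon-gamma lineage, made up 24.2% ± 2.84. Cycling-like cells made up 12.3% ± 1.47, naive or central memory-like cells 8.39% ± 1.40, Treg-like cells with Foxp3 3.52% ± 0.28, interferon response-like cells 1.37% ± 0.35 and B cell-like cells 1.27% ± 0.30. Clusters that met no marker rule held 7.30% ± 0.83. The Th1-like share was below the Tfh-like share in 5 of 5 mice, by a mean of -17.4 points ± 8.88 (two-sided exact sign-flip permutation p = 0.063, the smallest that 5 mice allow). The sort on CD11a and CXCR3 can set these shares, and doublets from 1 mouse can remain in them. With stricter cell quality the difference was -10.3 points and Tfh-like cells were more frequent in 4 of 5 mice, and the naive or central memory-like share was 13.9%. That share was 3.13% at resolution 1.5, 14.7% with cycle genes kept and 15.2% with hashtags called by share, the unnamed share was 17.9% at resolution 1.5 and 18.6% without Scrublet calls, and the interferon response-like share was 0.812% at resolution 0.6. The Th1-like share leaves out cycling cells, and 2 cycling-like clusters, of 731 and 454 cells, had 7 of 8 Th1-like markers raised, with Th1-like scores of 0.469 and 0.265 and Tfh-like scores of -1.58 and -1.91. The Tfh-like share includes a cluster of 906 cells, a mean of 7.38% of polyclonal cells. It had 4 of 8 Tfh-like markers raised and a Tfh-like score of 0.139, against 0.636 to 1.128 in the other Tfh-like clusters. The gap between the 2 shares depends on how these clusters were assigned.

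**Figure D1:**
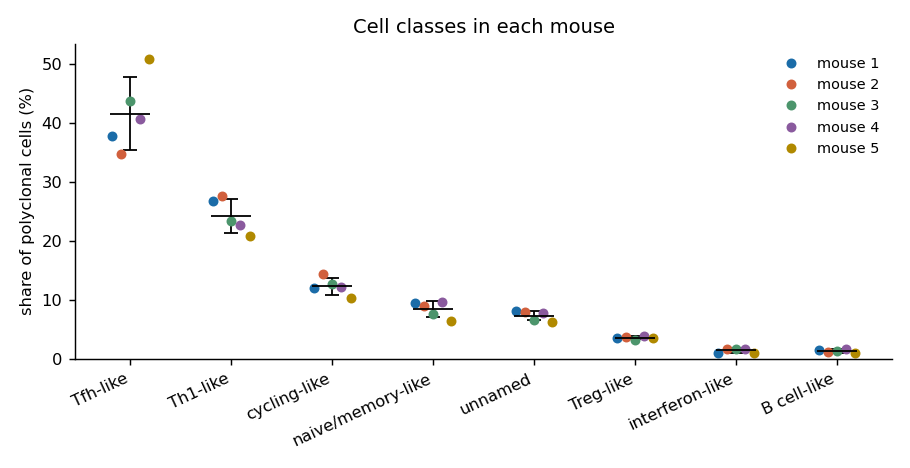
Share of polyclonal cells in each class (y axis, percent), with 1 point per mouse and a bar and whiskers for the mean ± SD of 5 mice. Tfh-like cells averaged 41.6% and Th1-like cells 24.2%.

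The genes with the highest ratios of Th1-like to Tfh-like cells of the same mice included a chemokine, a chemokine receptor and a granzyme. Ccl4, an inflammatory chemokine, was higher in Th1-like cells by a log2 fold change of 8.96 (SE 0.49, adjusted p = 8.80e-05), with 844 ± 476 CPM against 1.84 ± 1.88 (SD, n = 5 mice). Ccr2, a receptor for monocyte-attracting chemokines, was higher by 8.52 (SE 0.26), Klrg1, an inhibitory receptor of late effector cells, by 8.08 (SE 0.24) and Gzmb, the cytotoxic granule protease granzyme B, by 8.05 (SE 0.41). The long noncoding RNA Miat and Gcg, the gene of the glucagon precursor, were higher by 8.27 and 8.14. Ly6g, known as a neutrophil surface marker, had 1219 counts in Th1-like and 1 in Tfh-like cells, a ratio of 2033 (exact 95% counting interval 364 to 80350), and Nccrp1 had 706 and 1, a ratio of 1177 (211 to 46560).

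The genes with the lowest ratios included secreted factors and transcriptional regulators. Lif, a cytokine of the interleukin-6 family, had a log2 fold change of -5.65 (SE 0.25, adjusted p = 6.35e-12), Id3, an inhibitor of E protein transcription factors, -5.46 (SE 0.37) and Cebpa, a transcription factor best known in myeloid cells, -5.04 (SE 0.15). Sostdc1, a secreted antagonist of bone morphogenetic proteins, fell from 79.6 ± 18 CPM in Tfh-like cells to 1.81 ± 2.17 in Th1-like cells. Synpo, Nsg2, Padi4 and Fam43a had log2 fold changes of -5.18, -4.92, -4.83 and -4.73. Each of these genes changed the same way in 5 of 5 mice. Of the genes of the sorted proteins and CD4, Cxcr3 was higher in Th1-like cells by 0.43, Itgal, the gene of CD11a, by 0.36 and Cd4 by 0.94.

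Of 10038 genes tested, 3445 were higher and 3443 lower in Th1-like cells, and 982 and 972 of these differed by at least 2-fold. Each gene was tested in classes clustered without it, but correlated genes in the other part can still carry its signal, so the counts describe how far apart the classes lie and are not independent evidence of them. The 2 sets of classes differed, with 3569 and 2674 Th1-like and 4680 and 4535 Tfh-like cells, and the gene lists pool genes of both.

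**Figure D2:**
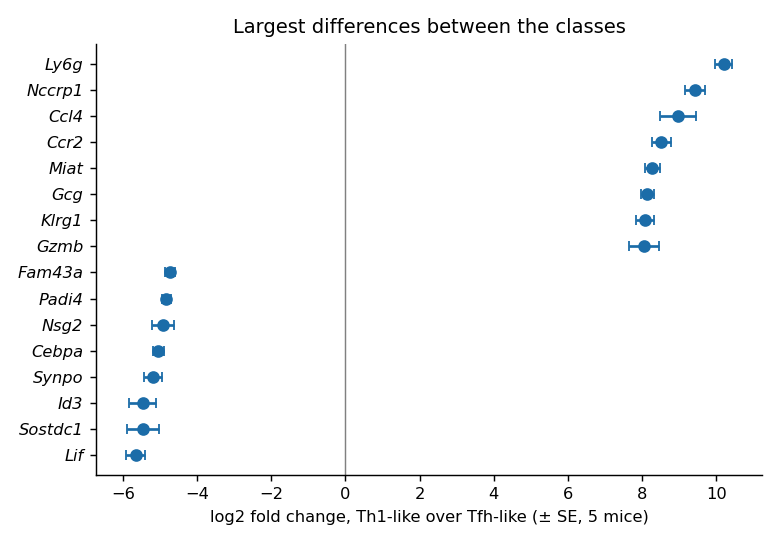
Log2 fold change of the 8 highest and 8 lowest named genes (x axis, Th1-like over Tfh-like) with SE over 5 mice. Ccl4 lay at 8.96 and Lif at -5.65; the fitted values of Ly6g and Nccrp1 rest on 1 count in Tfh-like cells and depend on the prior count.

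At the preset correlation of camera many gene lists differed between the classes, and with an estimated correlation none passed the threshold. Of 12 cytotoxic granule and killer receptor genes, 11 were higher in Th1-like cells and 1 lower (camera adjusted p = 1.52e-05; adjusted p = 0.145 with an estimated correlation). Among them were Ctsw, a granule cathepsin (log2 fold change 2.40, SE 0.06), and Fasl, the death receptor ligand (2.91, SE 0.10). Of 18 Th1 accessory genes 17 were higher and 1 lower (4.97e-09; adjusted p = 0.219 with an estimated correlation), including the galectin gene Lgals1 (3.51) and the interleukin-18 receptor subunit Il18rap (4.36). Migration receptors were higher in 11 of 14 and lower in 3 (0.00184; adjusted p = 0.299 with an estimated correlation), with the integrin subunit Itga4 at 3.37, the fractalkine receptor Cx3cr1 at 7.90 and Gpr183, an oxysterol receptor, at -3.23. The IL-10 or Tr1 programme had 8 of 10 higher and 2 lower (0.00693; adjusted p = 0.219 with an estimated correlation), with Il10 at 83.1 ± 28.7 CPM against 1.39 ± 0.474 and the repressor Prdm1 at 4.53. Type I interferon response genes were higher in 14 of 18 and lower in 2 (0.00266; adjusted p = 0.219 with an estimated correlation), with Ifit1bl1 at 5.55 and Ifi203 at 1.04. Oxidative phosphorylation genes were higher in 17 of 23 and lower in 2 (0.0137; adjusted p = 0.614 with an estimated correlation), by small folds such as 0.50 for Cox6a1 and 0.47 for Ndufa13.

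Lists with more members lower in Th1-like cells covered helper function and ribosome production. Of 14 follicular helper accessory genes, 13 were lower and 1 higher (7.48e-05; adjusted p = 0.236 with an estimated correlation), with Pou2af1, a transcriptional coactivator, at -3.96 and the nuclear factor Tox at -2.68. All 14 ribosome biogenesis genes were lower (4.74e-06; adjusted p = 0.299 with an estimated correlation), such as Npm1 at -1.67 and Fbl at -1.88. A Tfh-like cluster of 906 cells with 4 Tfh-like markers raised, singled out after its values were seen, was led by Srm, Myc and Nolc1. Lower too were all 22 ribosomal protein genes (3.55e-08; adjusted p = 0.323 with an estimated correlation), such as Rplp1 at -1.07. All 13 mitochondrial transcripts were lower (1.18e-04; adjusted p = 0.378 with an estimated correlation), with mt-Nd4l at -0.62. The counts of these 3 lists were the same with DESeq2 size factors and with no filter. T cell receptor signal genes were lower in 9 of 15 and higher in 1 (0.0274; adjusted p = 0.303 with an estimated correlation), with the transcription factor Irf4 at -1.58 and the receptor Tnfrsf18 at 1.20. S phase genes were lower in 21 of 40 and higher in 5 (0.00366; adjusted p = 0.614 with an estimated correlation), with Hells at -1.54 and Tyms at -1.09. Under stricter cell quality the median of that list turned from -0.24 to 0.08, and Hells, Tyms and Uhrf1 had values of 0.03, 0.19 and 0.17. Cells of cycling-like clusters were in neither class, so how cycling cells were assigned can enter that list.

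Other lists were divided. Inhibitory receptors had 5 higher and 4 lower of 9 (camera adjusted p = 0.523), with Havcr2, which encodes TIM-3, at 7.79, Entpd1, which encodes CD39, at 5.95 and Lag3 at 1.58. Secreted and ligand cytokines had 9 lower and 4 higher of 13 (0.134), with the RANK ligand Tnfsf11 at -4.21, Lta at -3.46 and Tnf at -1.32. Memory and quiescence genes had 6 higher and 4 lower of 12 (0.332), with Klf3 at 2.02 and Klf6 at 2.87. Glycolysis had 6 higher and 5 lower of 15 (0.954), with a median of -0.03, a mean of 0.13 and a negative test direction, and the glucose transporter Slc2a3 at 3.78. G2 and M phase genes had 12 lower and 6 higher of 32 (0.305), with Cks1b at -1.50, and the median of that list was positive under stricter quality and at resolution 1.5. Dissociation stress genes had 8 higher and 2 lower of 13 (0.321), with Dnajb1 at 0.42 and Hsp90aa1 at -0.38, the latter 0.02 at resolution 1.5. Adjusted over the list alone, each count was the same except S phase, with 20 lower. The fry test called inhibitory receptors (limma adjusted p = 6.60e-04), cytokines (0.00102), memory and quiescence (0.00124), G2 and M phase (0.0487) and dissociation stress (0.0287).

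Expanded clonotypes leaned toward the Th1-like programme. In clonotypes of 3 or more cells, Cx3cr1, the fractalkine receptor, was higher than in clonotypes of 1 cell by a log2 fold change of 1.55 (SE 0.14, adjusted p = 1.87e-11), S100a4, a calcium-binding protein of motile cells, by 1.59 (SE 0.11) and Ifng, the gene of interferon-gamma, by 1.14 (SE 0.09). Il7r, the survival receptor for interleukin-7, had a log2 fold change of -2.92 (SE 0.23, adjusted p = 7.32e-09), with 9.53 ± 6.60 CPM against 66.8 ± 12.4 (SD, n = 5 mice). Ccr7, the lymph node homing receptor, had -2.95 (SE 0.19), the survival gene Bcl2 -1.81 (SE 0.24) and Tcf7, which encodes TCF-1, -1.48 (SE 0.09). Each of these changed the same way in 5 of 5 mice. Serpinb1a, a serine protease inhibitor gene, was higher by 1.59 (SE 0.27, adjusted p = 2.80e-04), but was not called within Th1-like cells alone (0.70). Crmp1, Adam8, Tmem163, Miat and Nccrp1 were higher by 1.43 to 1.82, and Aff3, Gpr183, Nsg2, Ssbp2, Tespa1 and Usp18 lay between -1.81 and -1.48. Lrrc32, a Treg gene, had 0 counts in expanded against 251 in single-cell clonotypes, at least 6.12-fold lower, and Foxp3 had 5 against 1123 counts.

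Of 9993 genes tested, 845 were higher and 675 lower in expanded clonotypes. The DESeq2 test called 662 and 401, and clonotypes of 2 or more cells gave 1368 and 1123. The expanded group held 498 cells in 124 clonotypes, 24 to 253 per mouse, with a mean of median depths of 7371 UMIs against 6587 in 7672 single-cell clonotypes. Th1-like cells made up 53.7% of expanded and 22.3% of single-cell clonotypes, Tfh-like cells 23.1% and 45.9%, and naive or central memory-like cells 0.834% and 8.99% (two-sided exact sign-flip p = 0.063 each). Cycling-like cells made up 20.5% and 11.2%, higher in 5 of 5 mice, interferon response-like cells 0.277% and 1.49%, and unnamed cells, among them a cluster led by Il7r and NK receptor genes, 0.435% and 6.29%, both lower in 5 of 5 mice (exact sign-flip p = 0.063 each). Treg-like cells made up 0.833% and 3.65%, lower in 4 of 5 mice and higher in 1 (exact sign-flip p = 0.125). The expanded group held 3 naive or central memory-like, 2 interferon response-like, 4 unnamed and 1 Treg-like cell. Mice with few expanded cells can hold none of a rare class without a difference, so these directions per mouse say little. Without mouse 3, which held 253 of the cells, 488 genes were higher and 419 lower. Within Th1-like cells alone 9 genes were higher and 13 lower, and within Tfh-like cells alone 18 and 9, from 4 mice, since mouse 5 had 6 such expanded cells, under the minimum of 10.

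Among the lists, Th1-like markers were higher in 6 of 8 (camera adjusted p = 3.01e-09; adjusted p = 0.0485 with an estimated correlation), with Cxcr6 at 0.94 and Tbx21, which encodes T-bet, at 0.54. Th1 accessory genes were higher in 15 of 18, and 16 adjusted over the list alone (1.37e-15; adjusted p = 0.0485 with an estimated correlation), with Ahnak at 0.89 and Ly6a at 0.57. Migration receptors had 9 higher and 2 lower of 15, and 10 and 2 adjusted over the list alone (9.29e-06; adjusted p = 0.140 with an estimated correlation), with Itga4 at 1.01. Cytotoxic genes had 7 of 13 higher, and 7 higher and 1 lower adjusted over the list alone (9.91e-04; adjusted p = 0.173 with an estimated correlation), with Serpinb9 at 0.94. Inhibitory receptors had 5 higher and 4 lower of 9 (0.0761), with Havcr2 at 1.41 and Entpd1 at 1.08. The IL-10 or Tr1 programme had 4 of 10 higher (0.0120; adjusted p = 0.449 with an estimated correlation), with Prdm1 at 1.13. S phase genes had 8 of 40 higher, and 11 adjusted over the list alone (5.98e-04; adjusted p = 0.482 with an estimated correlation), with Rrm2 at 0.50, and cycling-like markers 2 of 6 (0.0292; adjusted p = 0.471 with an estimated correlation), with Top2a at 0.58. The fry test did not call S phase (limma adjusted p = 0.587), cycling-like markers (0.301) or the IL-10 or Tr1 programme (0.215), and called dissociation stress (0.0354). The larger share of cycling-like cells in expanded clonotypes can enter the S phase and cycling-like lists.

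Tfh-like markers had 5 lower and 1 higher of 8 (0.0120; adjusted p = 0.173 with an estimated correlation), with Tcf7 and Cxcr5, at -1.12, among the lower and Pdcd1, which encodes PD-1, higher by 0.69. Follicular helper accessory genes had 5 of 14 lower (0.00896; adjusted p = 0.303 with an estimated correlation), with Rgs10 at -1.07. Treg-like markers had 3 of 4 lower (0.00115; adjusted p = 0.140 with an estimated correlation), interferon response-like markers 3 of 5 (0.00896; adjusted p = 0.303 with an estimated correlation), with Isg15 at -0.57, and memory and quiescence genes 6 lower and 1 higher of 12 (0.0118; adjusted p = 0.480 with an estimated correlation), with Id3 at -1.48. Cytokine genes had 6 of 13 lower (0.0494; adjusted p = 0.449 with an estimated correlation), with Ltb at -1.02, and T cell receptor signal genes 7 lower and 1 higher of 15 (0.0120; adjusted p = 0.478 with an estimated correlation), with Egr1 at -0.69. Ribosome biogenesis had 9 of 14 lower (3.07e-06; adjusted p = 0.303 with an estimated correlation), ribosomal proteins 22 of 22 (1.91e-13; adjusted p = 0.173 with an estimated correlation) and mitochondrial transcripts 11 of 13 (3.51e-05; adjusted p = 0.348 with an estimated correlation), with Npm1 at -0.59, Rps24 at -0.55 and mt-Nd2 at -0.47. Naive or central memory-like markers had 2 higher, among them Klf2 at 0.76, and 3 lower of 5 (camera adjusted p = 0.693). Of genes of other cell types, the B cell genes Cd79a and Cd79b had 2.26 (adjusted p = 0.106) and 1.60 (0.324), the myeloid genes Itgam 1.62 (0.00292) and Cst3 0.42 (3.95e-04), the CD8 gene Cd8b1 4.04 ± 3.02 against 14.7 ± 2.92 CPM (2.95e-05), the NK gene Klrb1c -1.49 (1.53e-07) and Zbtb16 -0.52 (0.398); no erythroid marker was tested. Cd79a had 14.1 ± 23.3 CPM in expanded clonotypes, and its log2 fold change was 0.84 without mouse 3. Cd79b was lower in 4 of 5 mice, and B cell-like cells among expanded cells occurred in mouse 3 alone. Within Th1-like cells alone Itgam (0.57) and Cst3 (0.30) were not called. Type I interferon response genes had 3 higher and 3 lower of 18 (camera adjusted p = 0.739), glycolysis 4 higher and 1 lower of 15 (0.356), oxidative phosphorylation 2 of 23 higher (0.205), G2 and M phase 1 of 45 higher (0.105) and dissociation stress 1 of 13 lower, Jun at -1.34 (0.280). Adjusted over the list alone, the lower counts were 6 for Tfh-like markers, 4 for Treg-like and for interferon response-like markers, 6 for follicular helper accessory genes, 7 for memory and quiescence, 12 for ribosome biogenesis and 12 for mitochondrial transcripts, and cytokines had 1 higher and 7 lower, T cell receptor signal 2 and 7, type I interferon response 5 and 5, glycolysis 5 and 2, and G2 and M phase 0 and 0. Cxcr3 and Itgal had 0.10 and 0.18 (adjusted p = 0.489 and 0.0977), and Cd4 was higher by 0.39. Within Th1-like cells alone Usp18, Tbx21 and Ahnak, and within Tfh-like cells alone Tbx21, Serpinb9, Cxcr5 and Klf2, had a fold of the opposite sign. Leaving out 1 mouse ended the list calls of cycling-like markers (adjusted p = 0.0803 without mouse 3 and 0.382 without mouse 5), cytokines (0.0775 without mouse 4) and T cell receptor signal (0.0508 without mouse 5), and the gene calls of Gpr183 (-1.77 without mouse 2 and -1.78 without mouse 3), Cd8b1 (-1.27 without mouse 3) and Isg15 (-0.53 without mouse 5). Without mouse 1 Cd79a was called, at 2.83, and G2 and M phase passed without mouse 1 (0.0111) and mouse 2 (0.0490), as did oxidative phosphorylation without mouse 5 (0.0277). Without mouse as a block 16 of 95 named genes, among them Nccrp1 (1.67), Egr1 (-0.63) and Rrm2 (0.54), lost the call.

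The most frequent paired receptor of the pool, taken as that of the added transgenic cells, was found under all 5 hashtags, in 650 kept cells, 74 to 192 per mouse and 5.52% ± 2.89 of cells. It joined TRAV14D-1 and TRAJ15 with CDR3 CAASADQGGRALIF to TRBJ2-4 with CDR3 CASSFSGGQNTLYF, and its TRB was called TRBV26 in 731 barcodes and TRBV15 in 9. That V call is uncertain, since 318 of 430 cells with 3 or more GFP UMIs and mainly Trbv15 among their TRB variable transcripts had a TRB called TRBV26. A GFP UMI was present in 97.4% of these cells (exact 95% interval 95.8 to 98.5) and in 0.088% of 9127 other cells with a paired receptor, at mean median depths of 7247 and 6657 UMIs. The share of 5.52% can leave out added cells without an assembled receptor. Of 1085 kept cells with 3 or more GFP UMIs, 480 (44.2%) had no contig, against 15.4% of 11939 cells with no GFP UMI. An Apcdd1 UMI occurred in 86.25% of those 480 and in 86.6% of 633 transgenic-like cells with GFP. The labels describe neither GFP nor the specificity of the receptor, nor the gate of the transgenic cells, so differences from polyclonal cells, gated on CD11a and CXCR3, can include the gate.

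Transgenic-like cells also stood on the Th1-like side, and carried Apcdd1, which was almost absent from polyclonal cells. Apcdd1, which encodes a membrane-bound Wnt inhibitor, had 1590 counts against 2, a ratio of 10810 (exact 95% counting interval 2987 to 89310). Plscr3, a phospholipid scramblase family gene that lies 6758 bp from Tmem256 on chromosome 11, was higher by a log2 fold change of 2.86 (SE 0.12, adjusted p = 8.77e-22) and Tmem256 by 1.96 (SE 0.06). Serpinb1a, a serine protease inhibitor gene, was higher by 2.13 (SE 0.20, adjusted p = 2.65e-06), but was not called within Th1-like cells alone (1.25, adjusted p = 0.523). S1pr5, a sphingosine phosphate receptor, was higher by 1.96 (SE 0.15), Cx3cr1 by 1.67 and Ccl4 by 1.43. Il7r had a log2 fold change of -4.56 (SE 0.21, adjusted p = 1.44e-19), with 2.34 ± 0.56 CPM against 57.0 ± 8.92 (SD, n = 5 mice), Id3 -1.73 and the migration receptor Gpr183 -1.38. All changed the same way in 5 of 5 mice. Pltp was higher by 1.51, and Emb, Nsg2, Tnfsf14, Tespa1 and Rflnb lay between -1.59 and -1.29. Lrrc32 had 0 against 257 counts, at least 6.30-fold lower, and Foxp3 4 against 1206.

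Of 9992 genes tested, 942 were higher and 687 lower in transgenic-like cells, and without mouse as a block 624 and 481. The DESeq2 test called 708 and 414, and transgenic cells taken by GFP gave 1289 and 1096. Th1-like cells made up 51.2% of transgenic-like and 25.9% of other paired cells, Tfh-like cells 27.7% and 43.7%, naive or central memory-like cells 0.803% and 7.87%, Treg-like cells 0.0% and 3.34%, and unnamed cells 0.660% and 5.46% (two-sided exact sign-flip p = 0.063 each). Cycling-like cells made up 18.2% and 12.1%, higher in 4 of 5 mice (exact sign-flip p = 0.125). An unnamed cluster led by Il7r and NK receptor genes held 5.13% of the other paired cells and 0 of the transgenic-like cells. Of its cells with a TRA chain, 84.8% carried TRAV11-TRAJ18. Cells chosen by another TRA chain cannot carry that one as their main chain, so this absence was largely set by the definition. The cluster can enter the lower values of Il7r, Klrc1 and Zbtb16. Of genes of other cell types, the NK gene Klrb1c had -1.07 (adjusted p = 1.49e-05), Klrc1 -2.11 (0.0127), Zbtb16 -1.04 (0.0250), the myeloid genes Cst3 0.24 (0.0119) and Itgam 0.05 (0.966), and Cd8b1 0.28 (0.392). Zbtb16 was not called without mouse 1, 2, 3 or 4 (-1.31, -1.10, -0.96 and -0.91) or without the block (-0.96), nor with DESeq2 (-1.11), and Klrc1 not without mouse 1 or 3 (-1.51 and -2.15). Cst3 was not called without mouse 1 (0.22), in thinned cells (0.075), or within Th1-like (-0.04) or Tfh-like cells alone (0.18). Klrb1c had -0.01 within Tfh-like cells alone, and Cd8b1 was called, at 0.42, with transgenic cells taken by GFP. Thinned to 3000 UMIs per cell, 516 genes were higher and 336 lower; within Th1-like cells alone 51 and 23, and within Tfh-like cells alone 36 and 64.

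Th1-like markers were higher in 7 of 8, and 8 adjusted over the list alone (2.21e-09; adjusted p = 0.159 with an estimated correlation), with the interleukin-12 receptor subunit Il12rb2 at 1.06 and Ly6c2 at 0.89. Th1 accessory genes were higher in 16 of 18 (2.22e-13; adjusted p = 0.116 with an estimated correlation), with Anxa2 at 0.86 and Lgals1 at 0.81. Migration receptors had 10 higher and 3 lower of 15 (1.07e-04; adjusted p = 0.269 with an estimated correlation), with the integrin subunit Itga4 at 0.64, and cytotoxic genes 7 higher and 2 lower of 13 (0.00233; adjusted p = 0.269 with an estimated correlation), with Serpinb9 at 0.81, Klrg1 at 1.25 and the perforin gene Prf1 at 1.24. The IL-10 or Tr1 programme had 5 higher and 1 lower of 10 (0.0358; adjusted p = 0.523 with an estimated correlation), with Ctla2a at 0.57; the fry test did not call it (limma adjusted p = 0.173) and called memory and quiescence (0.0173). Inhibitory receptors had 5 higher and 2 lower of 9 (camera adjusted p = 0.114), with Entpd1 at 1.02. Tfh-like markers had 6 of 8 lower (3.33e-05; adjusted p = 0.269 with an estimated correlation), with Tcf7 at -1.06, and follicular helper accessory genes 7 lower and 1 higher of 14 (2.96e-04; adjusted p = 0.269 with an estimated correlation), with Rgs10 at -0.80. Treg-like markers were lower in 4 of 4 (5.76e-05; adjusted p = 0.159 with an estimated correlation) and cytokine genes in 5 of 13 with 1 higher (0.0216; adjusted p = 0.269 with an estimated correlation), with lymphotoxin Lta at -2.14. Interferon response-like markers had 2 of 5 lower (0.0358; adjusted p = 0.269 with an estimated correlation). Ribosome biogenesis had 12 of 14 lower (4.71e-09; adjusted p = 0.159 with an estimated correlation), ribosomal proteins 22 of 22 (3.50e-11; adjusted p = 0.269 with an estimated correlation) and mitochondrial transcripts 9 of 13 (7.02e-04; adjusted p = 0.462 with an estimated correlation), with Npm1 at -0.55, Rpl32 at -0.39 and mt-Nd2 at -0.29. Memory and quiescence genes had 4 lower and 2 higher of 12 (camera adjusted p = 0.115, and 0.0477 without the block), T cell receptor signal 4 lower and 1 higher of 15 (0.0513), type I interferon response 5 higher and 2 lower of 18 (0.202), glycolysis 5 higher and 1 lower of 15 (0.0903), oxidative phosphorylation 6 of 23 higher (0.0513, and 0.0478 without the block), S phase 1 of 40 higher (0.442), G2 and M phase 1 of 45 higher (0.412), dissociation stress 2 higher and 1 lower of 13 (0.229) and cycling-like markers 0 of 6 (0.360). Adjusted over the list alone, migration receptors had 11 higher and 3 lower, cytotoxic genes 8 and 2, cytokines 2 and 6, type I interferon response 5 and 3, glycolysis 7 and 2, dissociation stress 3 and 1, and oxidative phosphorylation 8 higher, while the lower counts were 9 for follicular helper accessory genes, 4 for interferon response-like markers, 13 for ribosome biogenesis and 12 for mitochondrial transcripts. Naive or central memory-like markers had 2 higher and 2 lower of 5 (0.486), with a median of 0.16 and a mean of -0.29. Cxcr3 had -0.12 (adjusted p = 0.200), and Itgal and Cd4 were higher by 0.24 and 0.31. Within Tfh-like cells alone Ly6c2, Anxa2, Lgals1 and Ctla2a had folds of -1.11, -0.38, -0.54 and -1.85, and mt-Nd2 had 0.04. The clustering can set part of such folds for genes that helped separate the classes. Itga4 had -0.08 within Th1-like and -0.43 within Tfh-like cells alone. Leaving out 1 mouse ended the calls of the IL-10 or Tr1 programme (adjusted p = 0.0915, 0.0666 and 0.105 without mouse 1, 2 and 5), interferon response-like markers (0.0674 and 0.0569 without mouse 2 and 4) and Ccl4 (1.39 without mouse 3). It brought T cell receptor signal (0.0248 and 0.0254) and oxidative phosphorylation (0.0388 and 0.0283) past the threshold without mouse 1 and 5, cycling-like markers (0.0155) and G2 and M phase (8.08e-04) without mouse 2, and S phase (0.00923) without mouse 5. Without mouse as a block 19 of 94 named genes, among them Ccl4, Klrg1, Itgal and Zbtb16, lost the call.

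**Figure D3:**
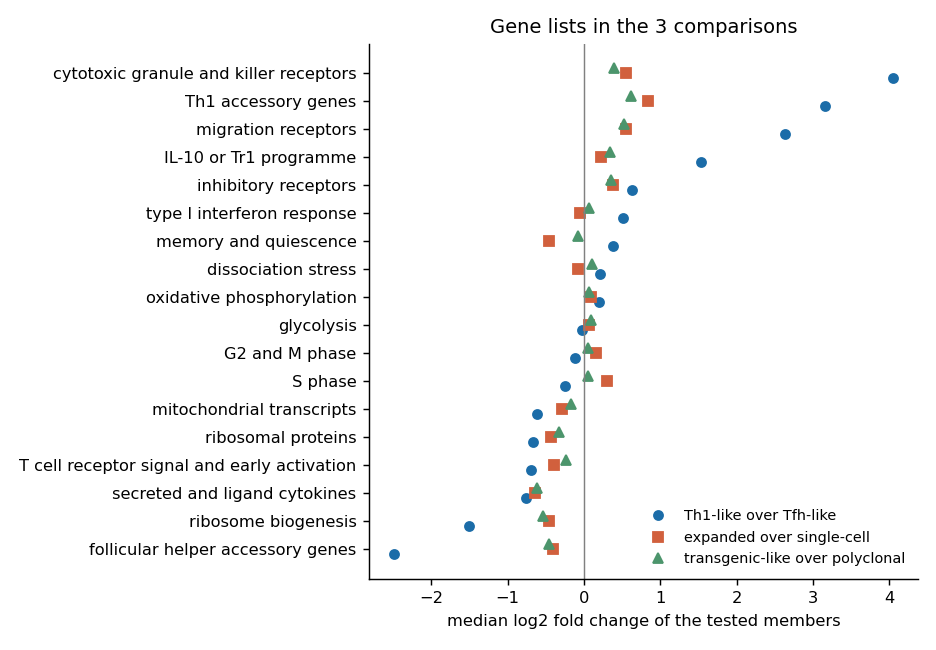
Median log2 fold change of the tested members of each gene list (x axis) in the 3 comparisons, with 1 symbol per comparison. Cytotoxic genes had the highest median between Th1-like and Tfh-like cells, 4.05, and 0.56 in expanded clonotypes.

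Cells of 1 clonotype shared a class more often than with class labels permuted among clonotypes of the same mouse. Among 400 polyclonal clonotypes with 2 or more Th1-like or Tfh-like cells, the share of same-class pairs averaged 66.6%, with each clonotype weighing equally. With class labels permuted among the cells of these clonotypes it averaged 52.4% (95% of permutations 48.1 to 56.7, two-sided permutation p = 0.0001, the smallest they can give). Both classes occurred in 152 clonotypes (38.0%), against 213.6 with labels permuted (196 to 231; permutation p = 0.0001). The share of same-class pairs, averaged over clonotypes, was 66.1%, 67.4%, 68.5%, 54.2% and 77.6% in mice 1 to 5. Of Th1-like and Tfh-like cells together, 69.9% ± 2.86 (SD, n = 5 mice) were Th1-like in expanded and 33.0% ± 5.63 in single-cell clonotypes, a difference of 36.9 points ± 7.03 in the same direction in 5 of 5 mice (two-sided exact sign-flip p = 0.063, the smallest possible).

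**Figure D4:**
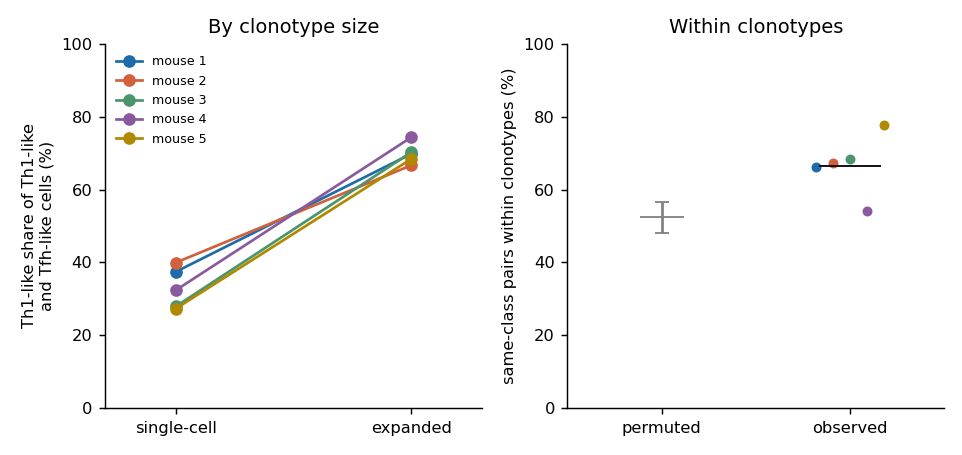
Left, Th1-like share of Th1-like and Tfh-like cells (y axis, percent) in single-cell and expanded clonotypes, 1 line per mouse. Right, same-class pairs within clonotypes, averaged over clonotypes (y axis, percent). The permuted mean and 95% range are in grey, the observed 66.6% is a black bar, and there is 1 point per mouse.

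V segment usage differed between Th1-like and Tfh-like clonotypes at few segments. With 2096 Th1-like and 3789 Tfh-like clonotypes counted, TRAV5-4 made up 3.84% ± 1.15 of Th1-like and 2.01% ± 0.63 of Tfh-like clonotypes (log2 fold change 0.91, SE 0.23, edgeR adjusted p = 0.00880, higher in 5 of 5 mice), and was the only one of 74 TRAV segments called. TRBV3, the only one of 21 TRBV segments called, made up 19.0% ± 1.14 and 14.6% ± 1.28 (0.32, SE 0.09, adjusted p = 0.0483, 5 of 5 mice). TRAV3D-3 had 0.84 (adjusted p = 0.0516) and TRAV9-4 -0.61 (0.533). TRBV13-2 had 1.52 (0.139) and TRBV16 -0.56 (0.200), and most contigs with TRBV13-2 carried a joint TRBV12-2 and TRBV13-2 call, at -0.11. TRAV5-4 was not called without mouse 1, 2 or 5, nor TRBV3 without mouse 1 or 3, so that 0 of the segments passed without mouse 1, with 4 TRAV and 3 TRBV segments at an unadjusted edgeR p under 0.05. Without mouse as a block TRBV13-2 and TRBV16 were called too.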

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

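The tests on Apcdd1, Plscr3 and Tmem256, the tests of Apcdd1 transcripts and of TRA chains in Trbv15 cells, and the test of random draws of cells, were chosen only after the result was seen.

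Apcdd1, Plscr3 and Tmem256 stayed higher in transgenic-like cells within each class, and the lowest of their 6 log2 folds was 1.78, which argues against class makeup. Apcdd1 UMIs occurred in 82.4% of 17 transgenic-like cells with no GFP UMI (exact 95% interval 56.6 to 96.2). They occurred in 0.020% of 10082 cells with another receptor and no GFP (median depths 5421 and 6529 UMIs). A cell whose GFP reads were all counted as Apcdd1 would also show no GFP UMI. These values thus cannot decide whether GFP reads were counted as Apcdd1, which stays open. Tmem256 (chromosome 11, 69838514 to 69839618) and Plscr3 (69846376 to 69852058) lie 6758 bp apart, closer than the closest pair in random sets of genes (permutation p = 0.0008), but this test was prompted by their nearness and cannot decide whether a change linked to a position may account for the pair. Of other genes within 1000 kb of Plscr3, 9 of 56 were called, 16.1% against 16.3% elsewhere, and of those near Apcdd1 (chromosome 18, 62922231 to 62961179) 0 of 5. The nearest of the 56, Kctd11, had the largest log2 fold change among them in size, 0.97, but was not called (edgeR adjusted p = 0.145). The nearest to Apcdd1, Napg, had -0.09 (edgeR adjusted p = 0.676). A share over the whole window can miss an effect on the nearest genes alone. The position of the transgene is not given in the sources used here, and a change linked to it, the sort and a regulation by the receptor stay open.

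Cells with 3 or more TRB variable UMIs, at least 80% of them Trbv15, and no GFP UMI mostly had no assembled receptor. A TRB contig was read in 11.1%, 13.2%, 8.08%, 11.9% and 16.7% of them in mice 1 to 5, against 84.5% to 94.8% over 19 other segments, and 249 such cells had none, while of 430 cells with Trbv15 and 3 or more GFP UMIs 74.9% had a TRB chain, 318 of them called TRBV26. The median gene expression UMI count of all 281 Trbv15 cells without GFP, 32 of them with a TRB contig, was 1.02 times that of other cells (ratio 1.022). This argues against low gene expression depth, with both groups chosen for 3 or more TRB variable UMIs. The depth of the receptor library per cell was not examined. Of the 249 cells 0.402% had an Apcdd1 UMI, which argues against transgenic cells without GFP. A TRA chain was present in 0.0% of the 249, with an exact 95% upper bound of 1.47% and a floor of 3 counts at 1.20%, against 8.20% of other cells without TRB, which argues against loss of the TRB chain alone. Receptors were also often missing in GFP cells as a whole: of 1085 kept cells with 3 or more GFP UMIs 44.2% had no contig, against 15.4% of 11939 with no GFP UMI. A processing step that dropped whole barcodes could account for the Trbv15 cells without a receptor and was not tested.

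Expanded and single-cell clonotypes differed at few genes within a class. Over the 1520 called genes the median signed log2 fold was 0.55, and the class makeup alone predicted 0.331. Over the 1349 of them tested within Th1-like cells it was 0.116, against 0.51 over all cells, and over the 1386 tested within Tfh-like cells, in 4 mice, 0.189 against 0.52. These genes were chosen over all cells, so the lower fold alone decides nothing, but 20 random draws of as many cells from all classes called at least 624 genes at the Th1-like and 268 at the Tfh-like cell numbers (edgeR), with medians of at least 0.42, against 22 and 27 genes within the classes, which argues against cell number as the whole cause. Class makeup is a candidate explanation of part of the difference, with the limit that the classes were made from the same expression, and an effect within classes stays open.

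The sums were also regrouped. Between Th1-like and Tfh-like cells 1 of 70 splits, the real one, called as many as 6888 genes and the highest other 0, but these groups were made from expression, so this decides nothing about chance. For expanded against single-cell clonotypes 1 of 100 splits, the real one, called as many as 1520 genes, and the highest other called 353. For transgenic-like against polyclonal cells 1 of 100 called as many as 1629, and the highest other 119. Most of these splits place both sums of some mice in 1 group. With mouse as a block, fewer mice then inform the difference, so fewer genes can be called. The share of 1 in 100 thus decides nothing about chance. Only 16 splits part every pair, too few for a share under 0.05; the highest of the others called 299 genes for expanded clonotypes and 0 for transgenic-like cells (edgeR; the real comparison had 2744 genes at an unadjusted p under 0.05 and DESeq2 called 708 higher and 414 lower).

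Of 277 groups of 5 values, 16 had a mouse far from the other 4, and chance alone gives about 1 in 20. The largest clonotype of mouse 3 held 36 cells, against 5 to 7 elsewhere. In log2 ratios, mouse 5 stood apart for Ctsw between the classes (2.65). Between expanded and single-cell clonotypes mouse 5, with 24 expanded cells, stood apart for Tbx21 (1.07), Cst3 (-0.038), Zbtb16 (-2.68), Klrg1 (2.68), Havcr2 (0.52), Rtp4 (0.60), Ndufb8 (-0.11), Cycs (-0.52), Rps24 (-0.38) and Dnajb1 (-0.32), and mouse 2 for Nolc1 (-0.36). In transgenic-like cells mouse 4 stood apart for Nsg2 (-1.06) and mouse 5 for S1pr4 (0.36) and Lta (-1.27).

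The transgenic effect differed between classes by an interaction test (edgeR) at 12 genes that were relatively higher in Th1-like and 1 gene relatively lower, of 8598 tested. Plscr3 differed by 1.16 (3.34 in Th1-like and 2.18 in Tfh-like cells, adjusted p = 0.0305) and Lgals1 by 0.60 (0.04 and -0.56, adjusted p = 6.16e-04). The classes in this test were clustered from all genes. A gene that helps separate the classes, as Lgals1 may at 3.51 between them, can have its fold within a class set partly by the clustering. Its interaction thus cannot be read as a transgenic effect alone. Signals that no comparison was set on were GFP UMIs in 1667 barcodes, the TRAV11-TRAJ18 receptor in 413 cells, 153 B cell-like cells and 62 cells of a cluster led by Lyz2. Such cells still entered the summed groups. Other paired cells held 19 B cell-like cells, and the cluster with most TRAV11-TRAJ18 cells made up 5.13% of them.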

How the results depend on the processing

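The alternatives added after the files were seen, chosen after seeing the data, were transgenic cells called by GFP, polyclonal cells without GFP, and expanded clonotypes without the largest of each mouse. Of 163 recomputed values of the comparisons 139 stayed within 1.5 times or kept the call. These include every recomputed class difference and Th1-like share by clonotype size. Their label was fixed in advance, since a sign-flip p over these mice cannot pass 0.05. Of 88 class shares 70 moved by less than 1 SD. Of 4265 values of named genes 3863 kept the call, and 309 lost and 33 gained it. The other 60 changed sign with the main or the recomputed value past the threshold. The cause was not tested except where said. Leaving out each mouse gave 488 to 915 higher and 419 to 695 lower genes in expanded clonotypes, the lowest without mouse 3, and 0 to 2 V segments. It gave 3160 to 3411 higher and 3109 to 3355 lower genes in Th1-like cells, 704 to 939 and 470 to 693 in transgenic-like cells, 65.5% to 68.6% same-class pairs, 36.2% to 39.2% clonotypes with both classes, 35.6 to 39.5 points more Th1-like cells in expanded clonotypes, a class difference of -19.9 to -14.2 points and 40 to 44 list calls. Without the replicate block 624 genes were higher in transgenic-like cells and 4 V segments were called, and memory and quiescence and oxidative phosphorylation passed there; 16 of 95 named genes lost and 1 gained the call in expanded clonotypes, 19 of 94 lost it in transgenic-like cells and none changed sign. DESeq2 called 401 lower genes in expanded clonotypes and 414 in transgenic-like cells. Clonotypes of 2 or more cells, a larger group, gave 1368 higher and 1123 lower. Thinning, which leaves fewer UMIs, gave 516 higher and 336 lower in transgenic-like cells, and calling these by GFP 1096 lower. Within Th1-like cells alone, with fewer cells, 9 genes were higher and 13 lower in expanded clonotypes and 51 and 23 in transgenic-like cells; within Tfh-like cells alone, where expanded sums came from 4 mice, 18 and 9, and 36 and 64. The naive or central memory-like share lay between 3.13% and 15.2% and the unnamed share between 6.32% and 18.6%. Of 42 list calls 2 held with the estimated correlation, and fry called 45, but fry lost S phase, cycling-like markers and the IL-10 or Tr1 programme in expanded clonotypes (limma adjusted p = 0.587, 0.301 and 0.215) and the IL-10 or Tr1 programme in transgenic-like cells (0.173). Changes of sign, as log2 folds, were between the classes Hells 0.025, Tyms 0.19 and Uhrf1 0.17 under strict quality and Hsp90aa1 0.023 at resolution 1.5. For expanded clonotypes within Th1-like cells they were Usp18 0.002, Tbx21 -0.009, Ctsw -0.074, Klrg1 -0.001, Myc 0.55, Zbp1 -0.076, Tox 0.27, Cd200 0.38, Ahnak -0.027, Bhlhe40 -0.001, Slc2a3 -0.18 and Nolc1 0.062, and within Tfh-like cells Tbx21 -0.35, Cxcr5 0.042, Klf2 -0.42, Il2ra 0.59, Irf7 0.17, Serpinb9 -0.072, Ctla4 -0.11, Tnfsf11 0.19, Tnfsf14 0.10, Zbp1 -0.059, Tox 0.30, Bhlhe40 -0.16, Ldha -0.11, Eno1 -0.15, Ndufb8 -0.020 and Cox6a1 -0.13. For transgenic-like cells within Th1-like cells they were Irf7 0.10, Cst3 -0.039, Cd160 0.44, Itga4 -0.079, Tnfrsf18 -0.026, S100a6 -0.032, Ncl 0.045, Dnajb1 -0.018, mt-Cytb 0.002 and mt-Nd1 0.065, and within Tfh-like cells Ly6c2 -1.11, Klf2 -0.017, S1pr1 -0.10, Il2ra 0.47, Ube2c -3.56, Irf7 0.017, Ctla2a -1.85, Itga4 -0.43, Zbp1 -0.12, Tox 0.15, Anxa2 -0.38, Lgals1 -0.54, S100a6 -0.10, Ldha -0.042, Ndufa13 -0.10, Rps24 0.017, Jun 0.72 and mt-Nd2 0.040. Of these, Ube2c, Ctla2a and Lgals1 passed the threshold within Tfh-like cells. Values within a class rest on classes clustered from all genes, so genes that helped separate the classes can be affected by that. The 24 expanded cells of mouse 5 limit what single genes show in that mouse.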

Other observations

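The tests of clonotypes within sub-clusters were planned before their result was seen, and the description of the TRAV11-TRAJ18 cells and the Th1-like cluster compared between transgenic-like and other cells were chosen after their values were seen.

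A cluster of 750 cells that met no marker rule carried transcripts of Il7r, the NK receptor genes Klrc1, Klrk1 and Klrd1, and Zbtb16, which encodes PLZF, a transcription factor of innate-like T cells. Of its 479 cells with a TRA chain, 84.8% carried TRAV11 joined to TRAJ18, the chain of invariant natural killer T cells, against 0.0738% of 9482 other cells. Of 396 such cells with a TRB chain, 52.5% had a call containing TRBV13-2, 13.4% TRBV29 and 10.4% TRBV1. They made up 4.09% ± 0.79 (SD, n = 5 mice) of cells with a TRA chain, from 2.87% to 4.98% per mouse. A Th1-like cluster led by Gzma, S1pr5 and Cx3cr1 held 7.96% ± 4.25 of transgenic-like and 1.19% ± 0.73 of other paired cells, with the transgenic-like share higher in 5 of 5 mice (two-sided exact sign-flip p = 0.063). Of the other clusters, a Th1-like one led by Ccl4, Ccl3 and Il10 (26.0% and 13.4%) and a cycling-like one (5.82% and 3.25%) were also higher in 5 of 5 mice (exact sign-flip p = 0.063 each).

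Within Th1-like cells, the share of pairs of 1 clonotype in the same sub-cluster averaged 63.4% over clonotypes, against 53.6% with labels permuted (permutation p = 0.0008). Cells of 1 clonotype may thus share a state finer than the class. Each of the 5 mice lay above 53.6%. That value pools the mice, whose sub-cluster shares differed, so it is not a mouse's own permuted share. Within Tfh-like cells the shares were 38.7% and 31.6% (permutation p = 0.0639), with 3 of 5 mice above the pooled permuted share. The bound set beforehand took a p of 0.05 or more as evidence against sharing, which was wrong: 114 clonotypes gave a permuted range of 24.2% to 39.1%, wide enough to hold the excess seen, and such a p does not show equal shares, so this stays open.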
